A study of Mus musculus with 6 samples.

How the data were processed

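RNA-seq of whole kidney from wild-type mice was deposited for 6 libraries made from total RNA, 2 labelled 2M and 4 labelled 24M in a study of natural aging. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

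The deposited values are FPKM per gene, per the file headers, in 2 tables. The table used for testing holds 2M_1, 2M_2, 24M_1 and 24M_2 and lists 12666 genes. A separate table holds 24M_3 and 24M_4 and lists 13606 genes. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mm10 build were used, with no role or order given. The annotation and the step that made the FPKM are not given in the sources used here. In the tested table the larger of the age-group means was at least 0.50 FPKM for every gene, so genes low at both ages are not in it. The separate table holds 38 genes at 0 in both libraries, and its filter is not stated. The tables share 12546 genes, with 120 genes in the tested table alone and 1060 in the separate table alone. Low FPKM values did not fall on whole-read steps, so the depth of each library is unknown and no interval from read counts can be given.

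Gene symbols were matched by Ensembl gene ID, ignoring the version; 18 IDs of the tested table and 27 of the separate table had no symbol. Coordinates and biotypes come from GENCODE annotation of GRCm38, the same assembly as mm10. The way reads were assigned between near-identical genes is not stated, so values of paralogous genes are uncertain. This applies to Cyp2a4 and Cyp2a5, Cyp2d12, Gsta1 and Gsta2, the Hba and Hbb genes, the H2 genes, Eif3j2 and the alpha-defensins.

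Because the tables were made separately, changes with age were tested only within the tested table, which left 2 libraries per age. Levels of 24M_3 and 24M_4 are given beside the others as values from a separate table. They also enter the counts set beside the calls, the search for outlying libraries of 24M and the comparisons between 24M_3 and 24M_4. Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested, 11437 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with age as the only term and empirical Bayes moderation with an intensity trend and robust variance. Benjamini-Hochberg FDR below 0.05 over all genes tested was the threshold. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Means are given as FPKM ± SD over 2 libraries per age. For genes listed at 0 in both libraries of an age, each library's value is given in place of a fold.

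How many called genes lay on the same side of both 2M libraries in the separate table was counted. After these counts were seen, an association test that treats the tables as independent was dropped, because both comparisons use the same 2M libraries. In its place, 50 simulations of unchanged genes with shared 2M libraries were run once.

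The plan had assumed that all 6 libraries could enter a single fit, and it named this limma model for the case that the values were FPKM. On simulated data with 200 changed genes among 11437, in the same arrangement of 2 libraries against 2, the fit recovered 77% of genes changed by 1 and 92% of genes changed by 2 on the log2 scale. Of its calls, 4.52% were false. The simulated genes varied independently of each other, so this rate may not hold where real genes move together.

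Before the data were examined, 40 gene lists were fixed for pathways, cell types and technical signs. Each list with at least 3 tested members was tested with limma's camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 36 lists. The lists of T and NK cell, B and plasma cell, neutrophil and adrenal cortex markers had fewer than 3 tested members and were tested, where they then had enough, only without the filter. Members past the threshold were counted over all genes tested and also adjusted over the list alone. With 2 libraries per age the fit has 2 residual degrees of freedom, and an inter-gene correlation estimated from them is imprecise.

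The genes named in the text follow a rule fixed before the data were examined. It takes Mcu, Cdkn1a, Cdkn2a, Kl and all members of the uniporter list. It adds the 10 genes with the largest log2 change in each direction among those past the threshold with a mean of at least 1 FPKM and no overlap between ages, leaving out predicted genes, pseudogenes and variable segments of immunoglobulin and T cell receptor genes. It further takes the 5 genes with the smallest p in each direction and up to 4 members of each list with the smallest p. The rule spoke of all 6 libraries, and it was applied to the 4 libraries of the tested table. Over all 6 libraries, 6 of the 10 largest increases and 9 of the 10 largest decreases also meet it. The text gives values for part of these genes. Genes named outside this rule are marked as chosen after their values were seen.

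Alternatives covered the pseudocount, the filter, quantile and median scaling, non-robust moderation, thresholds, each tested library left out in turn, and a block on the replicate number. For the lists they covered an estimated correlation, fry and the rank version of camera. A restriction to genes annotated as protein-coding, a fit without the intensity trend and a fit without the adipocyte, urothelium and red blood cell lists were added after seeing the data.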

Results

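Kidney transcriptomes of wild-type mice were measured by bulk RNA-seq at the ages labelled 2M (2 libraries) and 24M (4 libraries). The question was which transcripts differ between young and naturally aged kidney, with the mitochondrial calcium uniporter and tubular cell senescence named as the subject of the study. Values are FPKM, and the depth per library is unknown. The tested table gave FPKM sums of 286198 for 2M_1, 295286 for 2M_2, 290590 for 24M_1 and 293057 for 24M_2. In the separate table the sums were 302628 for 24M_3 and 335723 for 24M_4. Across the 12546 shared genes, Pearson's correlation of log2(FPKM + 1) was 0.989 and 0.990 between libraries of the same age in the tested table and 0.978 to 0.982 across ages. It was 0.894 to 0.939 between libraries of different tables and 0.951 between 24M_3 and 24M_4. These correlations are across genes, which are not independent replicates. Levels of 24M_3 and 24M_4 are therefore set beside the others as values from a table that was made separately, and they enter no test of change with age.

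Transcripts of the cytochrome P450 genes Cyp2d12, Cyp2a5 and Cyp2a4 and of the immunoglobulin J chain were higher in 24M kidney, while those of the urea transporter Slc14a2, the water channel Aqp4 and adipocyte markers were lower. Cyp2d12 had 24.4 ± 0.841 FPKM in 2M and 132 ± 13.0 in 24M (SD, n = 2 per age), a log2 change of 2.39 ± 0.09 (SE; limma adjusted p = 0.00181). Jchain, which links secreted IgA and IgM, had 0.963 ± 0.291 FPKM in 2M and 14.5 ± 3.13 in 24M (log2 change 2.97, limma adjusted p = 0.00844). Slc14a2, the urea transporter of the inner medulla, fell from 10.4 ± 0.625 to 2.68 ± 0.280 FPKM, a log2 change of -1.63 ± 0.10 (limma adjusted p = 0.00824). Of 11437 genes tested, 180 passed the threshold, 87 higher and 93 lower in 24M, and 78 of them changed by at least 1 on the log2 scale. At an unadjusted p below 0.05 there were 796 genes higher and 1137 lower. By limma no gene passed without 2M_1 or without 2M_2, a fit that assumes the lone 2M library to vary like the 24M pair, with 1215 and 1452 genes at an unadjusted p below 0.05. Most of the 180 calls were also lost without 24M_1, and most were lost without 24M_2. Every call of a single gene below therefore rests on having both 2M libraries, and the calls depend on the 24M libraries too.

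The 10 largest increases were those of Jchain, Egr2, Atf3, Cyp2d12, Slc7a12, Cyp2a5, Arc, Bola1, Aldh1a7 and Afmid. Bola1, a mitochondrial protein of iron-sulfur cluster handling, lies on chromosome 3 (96196588 to 96219709, minus strand) and had 5.61 ± 0.1999 FPKM in 2M and 23.9 ± 0.957 in 24M. Afmid, the arylformamidase of tryptophan breakdown, had 6.93 ± 0.0360 and 25.3 ± 0.298 FPKM. The retinaldehyde dehydrogenase relative Aldh1a7 had 3.38 ± 0.972 and 13.5 ± 1.14 FPKM, and Cyp2a5 had 30.8 ± 6.35 and 131 ± 28.5. Among the genes with the smallest p were also Cyp2a4, with 182 ± 2.05 FPKM in 2M and 400 ± 22.9 in 24M, and Azgp1, a secreted zinc-binding glycoprotein, with 56.7 ± 0.504 and 113 ± 0.428. The transcription factors Egr2 and Atf3 and the activity-induced gene Arc had 24M means of 6.91, 11.8 and 7.08 FPKM against 2M means of 0.297, 1.49 and 1.06. In the separate table, 24M_3 and 24M_4 lay above both 2M libraries for 6 of these 10 genes, and the exceptions were Egr2, Atf3, Arc and Afmid. Afmid stood at 15.4 FPKM in 24M_3 and 5.24 in 24M_4.

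The 10 largest decreases were those of Cfd, Eif3j2, Aldh1a3, Cox8b, Akr1c18, Hbb-bt, Adipoq, Akr1b3, Cidea and Paqr5. Aldh1a3, a retinaldehyde dehydrogenase that makes retinoic acid, had 9.91 ± 0.972 FPKM in 2M and 0.347 ± 0.306 in 24M. Akr1b3, the mouse aldose reductase, which makes the osmolyte sorbitol, fell from 18.3 ± 0.928 to 4.21 ± 1.28 FPKM. Akr1c18, a hydroxysteroid dehydrogenase, fell from 22.6 ± 3.26 to 3.45 ± 0.865, and Paqr5, a membrane progestin receptor, from 22.3 ± 5.34 to 5.68 ± 0.807. Eif3j2 was listed at 11.4 and 9.55 FPKM in the 2M libraries and at 0 in 24M_1, 24M_2 and 24M_4, with 4.44 in 24M_3. Its reads can be shared with the closely related Eif3j1, so this value is uncertain. The smallest p values also took in Thrsp, a regulator of lipid synthesis, which fell from 8.07 ± 0.0235 to 2.31 ± 0.0269 FPKM, and Mob1a, a Hippo pathway adaptor, which fell from 14.2 ± 0.911 to 5.04 ± 0.246. For 9 of these 10 genes the levels of 24M_3 and 24M_4 in the separate table also lay below both 2M libraries, and Paqr5, at 19.6 and 18.6 FPKM, was the exception.

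**Figure D1:**
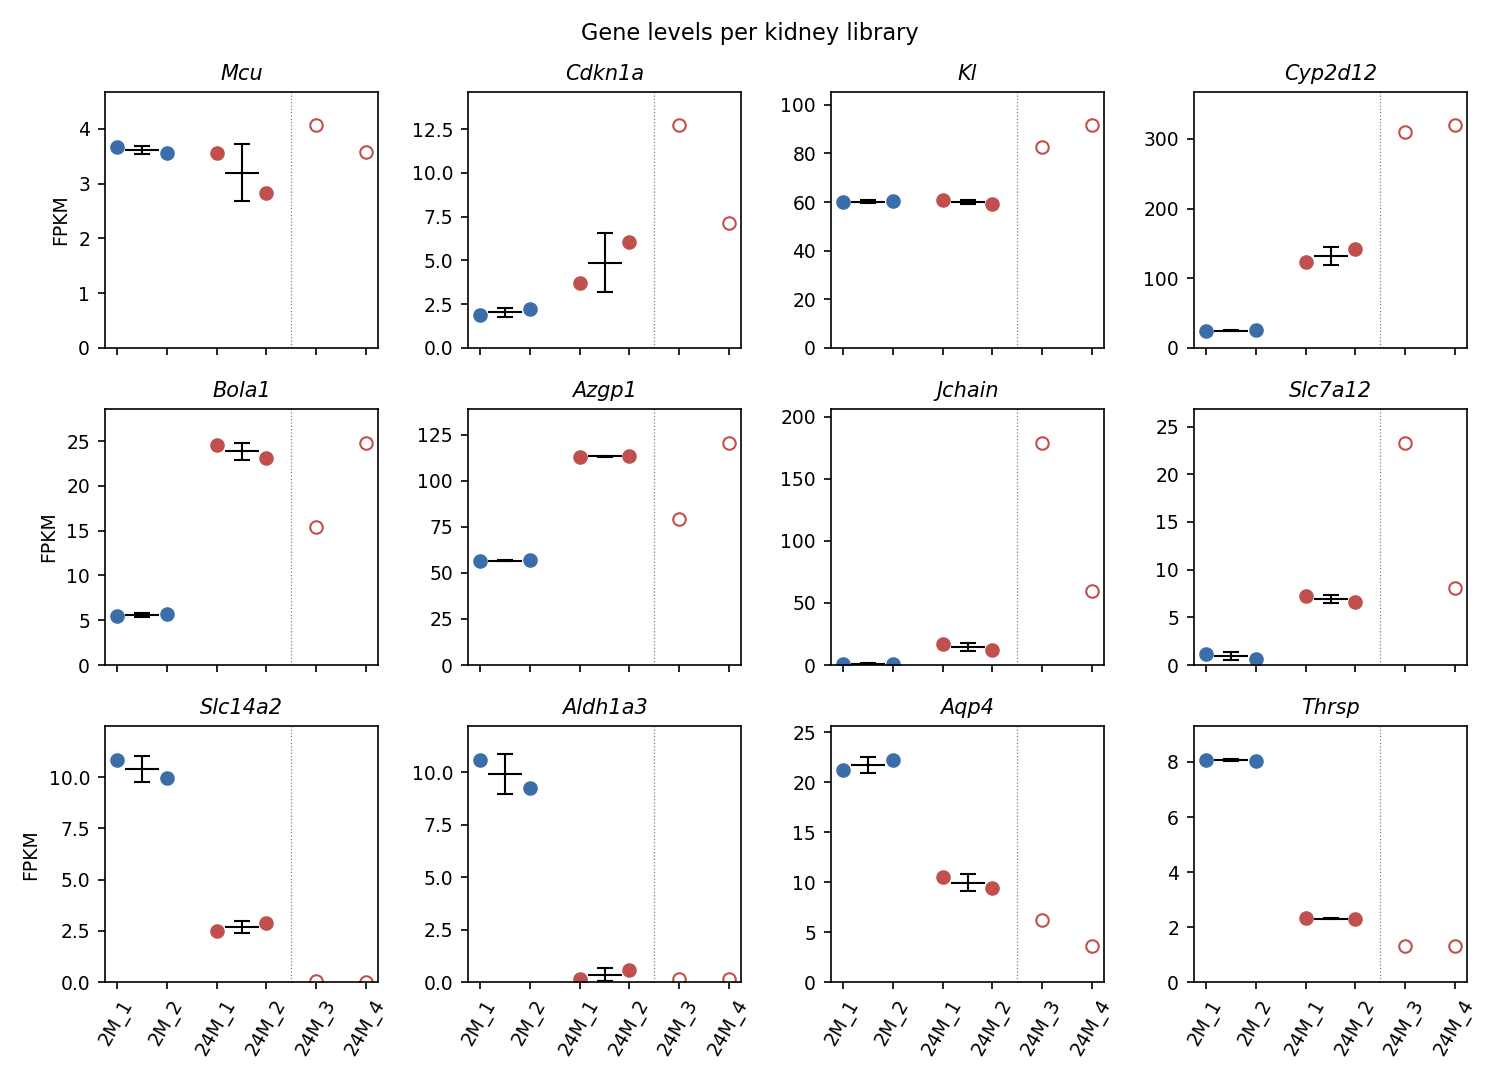
Levels in FPKM (vertical axes, each starting at 0) of 12 genes in each kidney library (horizontal axes). Blue points are 2M, filled red points are 24M libraries of the tested table, open red points right of the dotted line are 24M libraries of the separate table, and black marks give the mean and SD of 2 libraries. Mcu lies between 2.83 and 4.07 FPKM in all 6 libraries, whereas Slc14a2 lies at 9.97 FPKM or more in both 2M libraries and at 2.88 or less in the 24M libraries.

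The transcript of the uniporter pore did not pass the test. Mcu (ENSMUSG00000009647, chromosome 10, 59446984 to 59616692, minus strand) had 3.61 ± 0.0738 FPKM in 2M and 3.20 ± 0.523 in 24M (SD, n = 2 per age). Its log2 change was -0.14 ± 0.12 (SE), with a 95% interval of -0.44 to 0.16 and a limma adjusted p of 0.611. The change was -0.27 without 24M_1 and -0.01 without 24M_2, and 24M_3 and 24M_4 were at 4.07 and 3.59 FPKM in the separate table. Of the 13 members of the list for the uniporter and mitochondrial calcium handling, all tested, none passed in either direction, and none passed adjusted over the list alone. The regulatory subunit Micu2 had 45.5 FPKM on average in 2M and 40.3 ± 1.28 in 24M (log2 change -0.17, limma adjusted p = 0.281). The dominant-negative subunit Mcub had 1.30 and 1.64 FPKM (adjusted p = 0.488) and Micu3 4.54 and 5.24 (0.446). The scaffold subunit Smdt1 had 76.2 and 73.9 FPKM (adjusted p = 0.762) and the sodium-calcium exchanger Slc8b1 2.59 and 1.67 (0.325). Adjusted p values of Mcur1, Letm1, Slc25a23, Vdac1, Vdac2 and Vdac3 lay between 0.820 and 0.998. The list as a whole had a camera adjusted p of 0.940, with a median log2 change of -0.00085.

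The list of senescence and cell cycle inhibitors did not pass the camera test. Cdkn1a, which encodes the cell cycle inhibitor p21, had 1.86 and 2.20 FPKM in the 2M libraries and 3.70 and 6.06 in 24M_1 and 24M_2, a log2 change of 0.93 ± 0.21 (limma adjusted p = 0.131). The separate table gave 12.7 and 7.13 FPKM for 24M_3 and 24M_4. Cdkn2a is not among the genes listed in the tested table. Kl, the kidney-derived anti-aging factor klotho, had 60.2 ± 0.492 FPKM in 2M and 59.96 ± 0.972 in 24M (log2 change -0.0046, limma adjusted p = 0.980). Of 17 tested members of the list of senescence and cell cycle inhibitors none passed over all genes and 1, Mdm2, passed adjusted over the list alone, with 15.03 ± 1.14 FPKM in 2M and 21.3 ± 0.3797 in 24M (adjusted p = 0.0634 over all genes). In 24M_3 and 24M_4 of the separate table Mdm2 stood at 12.8 and 11.3 FPKM, below both 2M libraries. The camera adjusted p of the list of senescence and cell cycle inhibitors was 0.829. With fry in either direction, by which 25 lists passed, its adjusted p was 0.0238. The 13 tested senescence-associated secreted factors had a median log2 change of 0.21 and a camera adjusted p of 0.00019 (adjusted p = 0.564 with an estimated correlation). With a library left out, the median ran from 0.17 without 24M_1 (11 members tested) to 0.34 without 2M_2 (12 members tested). None of the 13 factors passed over all genes and 4 did adjusted over the list alone. Ccl2, a monocyte chemokine, had 0.205 and 0.908 FPKM in 2M and 2.71 and 5.62 in 24M. The mean log2(FPKM + 1) of this list was 1.93 and 2.03 in 2M, 2.19 and 2.45 in 24M_1 and 24M_2, and 3.58 and 1.97 in 24M_3 and 24M_4 of the separate table.

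The list of immediate-early and heat shock genes had the smallest camera p of the lists tested. Of 19 tested immediate-early and heat shock genes, 2 were higher in 24M over all genes and 10 adjusted over the list alone, and none was lower; the median log2 change was 1.07 (camera adjusted p = 2.55e-13, adjusted p = 0.564 with an estimated correlation). Ier2 had 4.21 ± 0.824 FPKM in 2M and 14.1 ± 0.824 in 24M, and the transcription factor Klf6 13.9 ± 1.23 and 25.4 ± 0.479. The 2M libraries differed from each other in this list, with a mean log2(FPKM + 1) of 3.61 in 2M_1 and 4.50 in 2M_2 against 5.31 and 5.38 in 24M_1 and 24M_2, and the separate table gave 4.55 and 3.60. Of 18 endoplasmic reticulum stress genes, 2 were higher and none lower, 7 adjusted over the list alone (camera adjusted p = 7.21e-05, adjusted p = 0.564 with an estimated correlation). Those 2 were Atf3 and the chaperone Dnajb9, which had 28.2 ± 0.248 FPKM in 2M and 46.0 ± 5.93 in 24M. The list's mean log2(FPKM + 1) was 4.79 and 4.83 in 2M and 5.15 and 5.22 in 24M_1 and 24M_2, but 4.73 and 4.61 in 24M_3 and 24M_4 of the separate table, below both 2M libraries. Of 22 antioxidant defence genes, the glutathione transferases Gsta2 and Gsta1 were higher, with 156 ± 2.996 against 239 ± 24.5 and 3.39 ± 0.0265 against 7.29 ± 1.31 FPKM. In that list 7 genes passed adjusted over the list alone, none was lower and the camera adjusted p was 0.00015 (adjusted p = 0.564 with an estimated correlation). Its means were 6.30 and 6.33 in 2M, 6.49 and 6.48 in 24M_1 and 24M_2, and 6.43 and 6.36 in 24M_3 and 24M_4, where Gsta2 stood at 183 and 60.1 FPKM and Gsta1 at 7.95 and 2.56.

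The water channel Aqp4, the urea transporter Slc14a2 and the epithelial adhesion molecule Epcam were lower in 24M, each a marker of the collecting duct or the loop of Henle. Of 17 collecting duct markers, 1 was lower and none higher, also adjusted over the list alone, with a median log2 change of -0.28 (camera adjusted p = 7.21e-05, adjusted p = 0.564 with an estimated correlation). The list's mean log2(FPKM + 1) was 3.94 and 3.91 in 2M and 3.57 and 3.59 in 24M_1 and 24M_2, but 4.03 and 3.88 in 24M_3 and 24M_4 of the separate table, near the 2M level. The lower gene was Aqp4, at 21.7 ± 0.755 FPKM in 2M and 9.96 ± 0.821 in 24M. Of 10 loop of Henle markers, Slc14a2 and Epcam were lower, 4 genes adjusted over the list alone, and none was higher (camera adjusted p = 0.0116, adjusted p = 0.780 with an estimated correlation). Epcam had 74.2 ± 3.41 and 46.2 ± 2.14 FPKM. The call of the loop of Henle list ended without 2M_1 (adjusted p = 0.137), without 24M_1 (0.0993) and by ranks (0.0682), and over all alternatives its adjusted p ran from 0.000638 to 0.780. Of 13 endothelial markers, the angiopoietin receptor Tek was lower, at 18.5 ± 1.76 and 11.7 ± 0.133 FPKM, 4 genes adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.780 with an estimated correlation). That call ended without 2M_1 (adjusted p = 0.295), without 24M_2 (0.2502) and by ranks (0.0882), with a range of 0.00726 to 0.780. Urothelium markers, from the lining of the renal pelvis, had a mean log2(FPKM + 1) of 2.87 and 2.60 in 2M, 0.105 in 24M_1 and 2.02 in 24M_2, and none of the 8 passed. In 24M_3 and 24M_4 of the separate table that mean was 0.353 and 0.314, and Slc14a2 stood at 0.0673 and 0 FPKM. How much inner medulla and renal pelvis each sample held is not given. A difference in dissection was not tested and cannot be told apart from age for these genes.

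Adipocyte markers were lower in 24M_1 and 24M_2 than in the 2M libraries. Of 7 tested adipocyte markers, 6 were lower and none higher, and all 7 were lower adjusted over the list alone (camera adjusted p = 2.43e-09, adjusted p = 0.564 with an estimated correlation). Without 2M_1 or without 2M_2 the list kept 1 tested member and could not be tested. The lipid droplet protein gene Cidea had 3.77 ± 0.601 FPKM in 2M and 0.361 ± 0.0218 in 24M. Adiponectin (Adipoq) was listed at 2.46 and 3.43 FPKM in 2M and at 0 in 24M_1 and 24M_2, with 0 and 0.660 in the separate table. Complement factor D (Cfd) was listed at 8.37 and 13.8 FPKM and at 0, with 4.81 in 24M_4, and the brown fat uncoupler Ucp1 at 1.69 and 1.89 and at 0. None of 8 urothelium markers passed, also adjusted over the list alone, although the list did at a median log2 change of -1.44 (camera adjusted p = 0.00075, adjusted p = 0.780 with an estimated correlation). The median was -0.60 without 24M_1 and -2.24 without 24M_2. The uroplakin Upk1b had 8.22 and 7.32 FPKM in 2M, 0 in 24M_1 and 2.61 in 24M_2, and Krt5 had 4.16, 3.37, 0.0679 and 1.73. Of 6 red blood cell markers, Hbb-bt was lower, at 25.5 ± 4.11 and 4.47 ± 1.66 FPKM, 5 genes adjusted over the list alone and none higher (camera adjusted p = 1.04e-05, adjusted p = 0.564 with an estimated correlation). The mean log2(FPKM + 1) of this list was 4.52 and 4.16 in 2M, 2.30 and 2.92 in 24M_1 and 24M_2, and 4.28 and 4.01 in 24M_3 and 24M_4 of the separate table, where Hbb-bt stood at 20.8 and 15.3 FPKM. Without the members of these 3 lists, an alternative added after seeing the data, 173 genes passed. That fit only takes out the list members, of which 6 adipocyte markers and 1 red blood cell marker had been called. It cannot tell whether the remaining calls depend on how much fat, blood or renal pelvis each sample held.

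**Figure D2:**
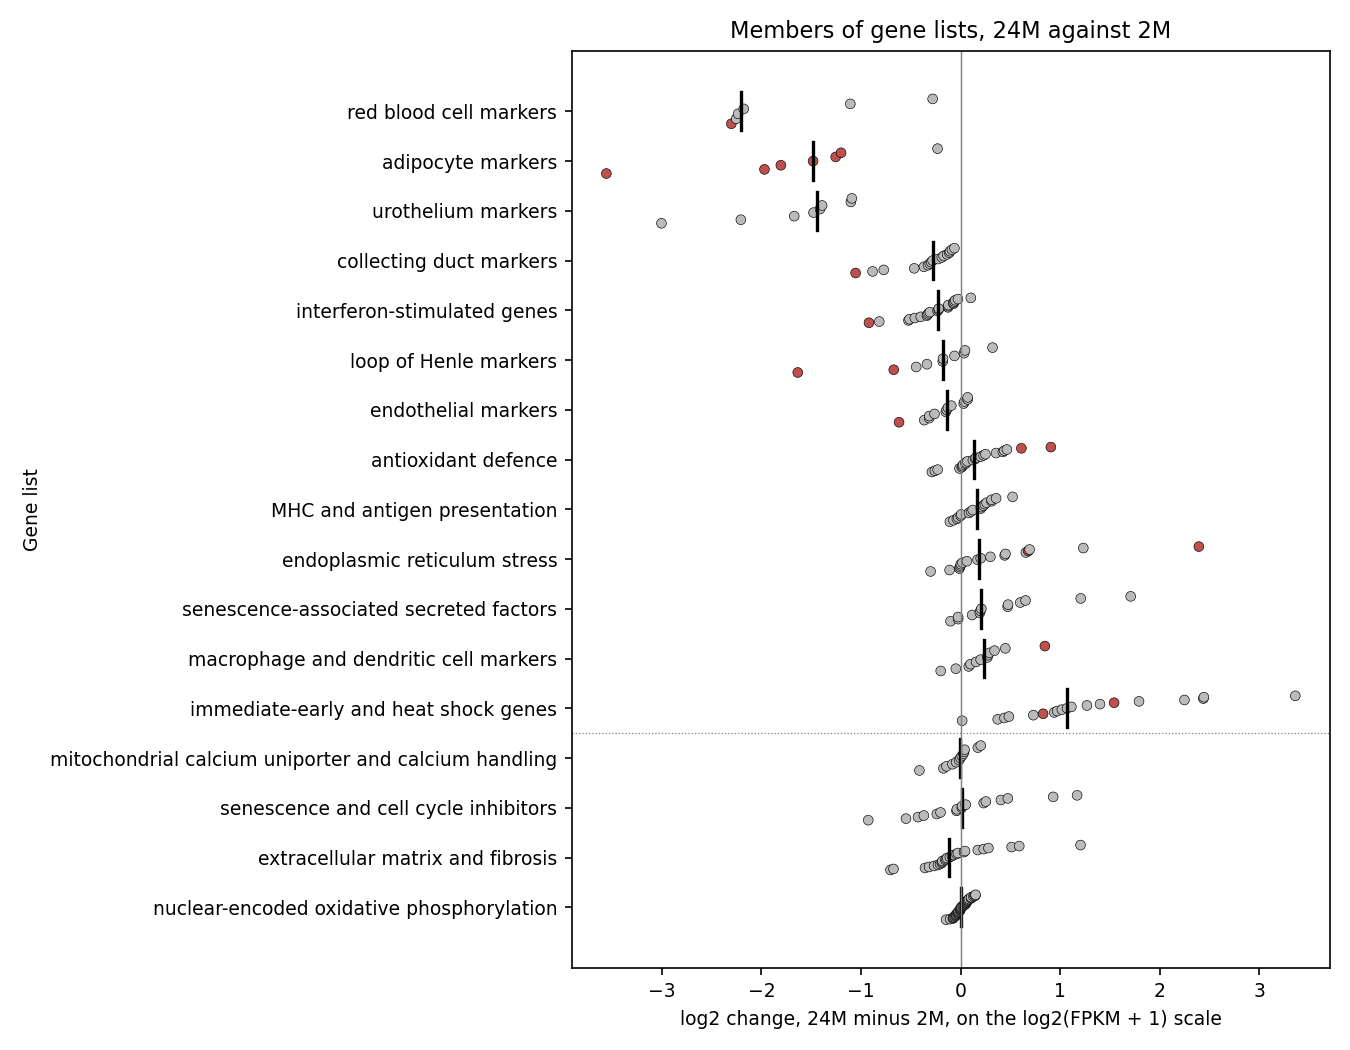
Log2 change of each tested list member, 24M minus 2M on the log2(FPKM + 1) scale (horizontal axis), by gene list (vertical axis). Red points passed the threshold over all genes, grey points did not, and black bars are medians. The 13 lists above the dotted line passed the camera test at the preset correlation, none of them with an estimated correlation (smallest adjusted p 0.564), and the 4 lists below it did not. The median of the immediate-early and heat shock list is 1.07 and that of the adipocyte list is -1.48.

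C1qa, a chain of complement C1q, was higher and the interferon-stimulated gene Ifit3 lower in 24M. Of 12 macrophage and dendritic cell markers, C1qa was higher, at 5.47 ± 0.248 FPKM in 2M and 10.6 ± 0.346 in 24M, and it was the single gene adjusted over the list alone. None was lower, and the camera adjusted p was 0.00114 (adjusted p = 0.726 with an estimated correlation), or 0.0722 without 2M_1, within a range over alternatives of 0.00015 to 0.726. Of 18 MHC and antigen presentation genes none passed over all genes and 3 were higher adjusted over the list alone, with a median log2 change of 0.16 (camera adjusted p = 0.00064, adjusted p = 0.564 with an estimated correlation), or a median of 0.086 without 2M_1. The class II gene H2-Ab1 had 42.9 and 50.3 FPKM in 2M and 70.9 and 63.7 in 24M. Of 22 interferon-stimulated genes, Ifit3 was lower, at 25.9 ± 1.11 and 13.2 ± 0.0275 FPKM, 2 genes adjusted over the list alone and none higher, with a median of -0.23 (camera adjusted p = 0.00019, adjusted p = 0.564 with an estimated correlation). The library 24M_3 of the separate table lay far above the other libraries, at a mean log2(FPKM + 1) of 4.93 for interferon-stimulated genes, 7.04 for antigen presentation and 4.40 for macrophages, against 1.97, 4.16 and 2.44 in 24M_4. Ifit3 stood at 86.6 FPKM in 24M_3 and 4.85 in 24M_4, and H2-Ab1 at 734 and 68.5. Jchain, the single tested B and plasma cell marker, stood at 179 and 59.5 FPKM there.

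The remaining 23 lists that were tested did not pass, and 6 of their 370 tested members were higher and 4 lower. The proximal tubule list lay at the threshold (camera adjusted p = 0.05001), with 1 of 22 members higher and 3 adjusted over the list alone. That member was the organic anion transporter Slc22a8, at 76.7 ± 0.895 FPKM in 2M and 102 ± 3.14 in 24M. The list passed without filter (adjusted p = 0.0403), without 2M_2 (0.0050) and without 24M_2 (0.00189), within a range of 0.00189 to 0.825. Of 11 distal tubule markers the sodium chloride cotransporter Slc12a3 was higher, also adjusted over the list alone, at 54.3 ± 2.74 and 74.3 ± 0.214 FPKM. Among 27 fatty acid oxidation genes the peroxisomal thiolase Acaa1b was higher, also adjusted over the list alone, at 74.3 ± 1.34 and 105 ± 7.91. Of 23 Wnt signalling genes Wnt4 was lower, at 3.25 ± 0.0770 and 0.552 ± 0.365, with 3 genes adjusted over the list alone. The clock genes Bhlhe40 and Per1 were higher, with 17.6 ± 3.30 against 59.5 ± 8.76 and 2.04 ± 0.660 against 5.75 ± 0.625 FPKM, and adjusted over the list alone 3 clock genes were higher and 5 lower. Among 10 male-biased kidney genes Acsm3 and Slco1a1 were lower, at 142 ± 9.52 against 73.8 ± 11.4 and 106 ± 16.2 against 58.8 ± 1.75, with 3 adjusted over the list alone. Of 5 female-biased genes the amino acid transporter Slc7a12 was higher and the anion transporter Slc22a7 lower, with 2 higher and 1 lower adjusted over the list alone. Y-linked Ddx3y was listed in every library, at 13.4 to 20.3 FPKM.

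Fibrosis, respiratory chain and injury lists did not pass the camera test in the main fit, and none of their members passed over all genes. With fry in either direction the extracellular matrix and tubular injury lists passed (adjusted p = 0.0200 for each). The nuclear-encoded oxidative phosphorylation list did not pass by fry in either direction (adjusted p = 0.392). Of 26 extracellular matrix genes none passed over all genes, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.4997). Col3a1 had 5.78 and 6.49 FPKM in 2M and 3.24 and 3.71 in 24M_1 and 24M_2 (limma adjusted p = 0.0564). The separate table gave 7.30 and 6.27 FPKM for Col3a1 in 24M_3 and 24M_4, not below the 2M level. None of 42 nuclear-encoded oxidative phosphorylation genes passed (camera adjusted p = 0.197), nor did any of 13 mitochondrially encoded genes (0.940) or 16 tricarboxylic acid cycle genes (0.829), also adjusted over the list alone. The nuclear-encoded list passed without 2M_2 (adjusted p = 0.0208) and the mitochondrially encoded list without 2M_1 (0.00803). Other lists that passed under an alternative were proliferation without filter (adjusted p = 0.0266), renin-angiotensin without 24M_1 (0.0363), Wnt signalling without 24M_2 (0.0225) and male-biased genes without 2M_1 (0.0228) or 24M_2 (0.0414). Without filter, lists with too few members otherwise could be tested, and 7 T and NK cell markers (adjusted p = 0.015) and 3 B and plasma cell markers (0.0302) passed as higher lists, while 3 neutrophil markers (0.326) did not. Of 18 tubular injury genes none passed, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.829). The log2 change was above 0 for 9 of them and below 0 for 9. A test for a shift of the whole list in a common direction therefore does not show that injury transcripts were unchanged. Havcr1, chosen after its values were seen, had 0.599 and 0.652 FPKM in 2M and 2.25 and 5.65 in 24M_1 and 24M_2. It stood at 14.4 and 11.1 FPKM in 24M_3 and 24M_4 of the separate table. The complement list (adjusted p = 0.523), the podocyte list (0.798), the fibroblast and mural cell list (0.792) and the renin-angiotensin list (0.413) had no member past the threshold over all genes. Adjusted over the list alone, complement had 3 higher and 2 lower, fibroblast and mural cell markers 1 higher and 2 lower, renin-angiotensin 1 lower and podocyte markers none. No member passed over all genes in the lists of proliferation (0.0794), mitochondrial dynamics (0.611), longevity-linked genes (0.829), ribosomal proteins (0.829) and sex chromosome genes (0.829), where adjusted over the list alone 1 longevity-linked gene was lower. The median, mean and test differed in sign for 7 of the 23 lists that did not pass and for 0 of the 13 that did.

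**Figure D3:**
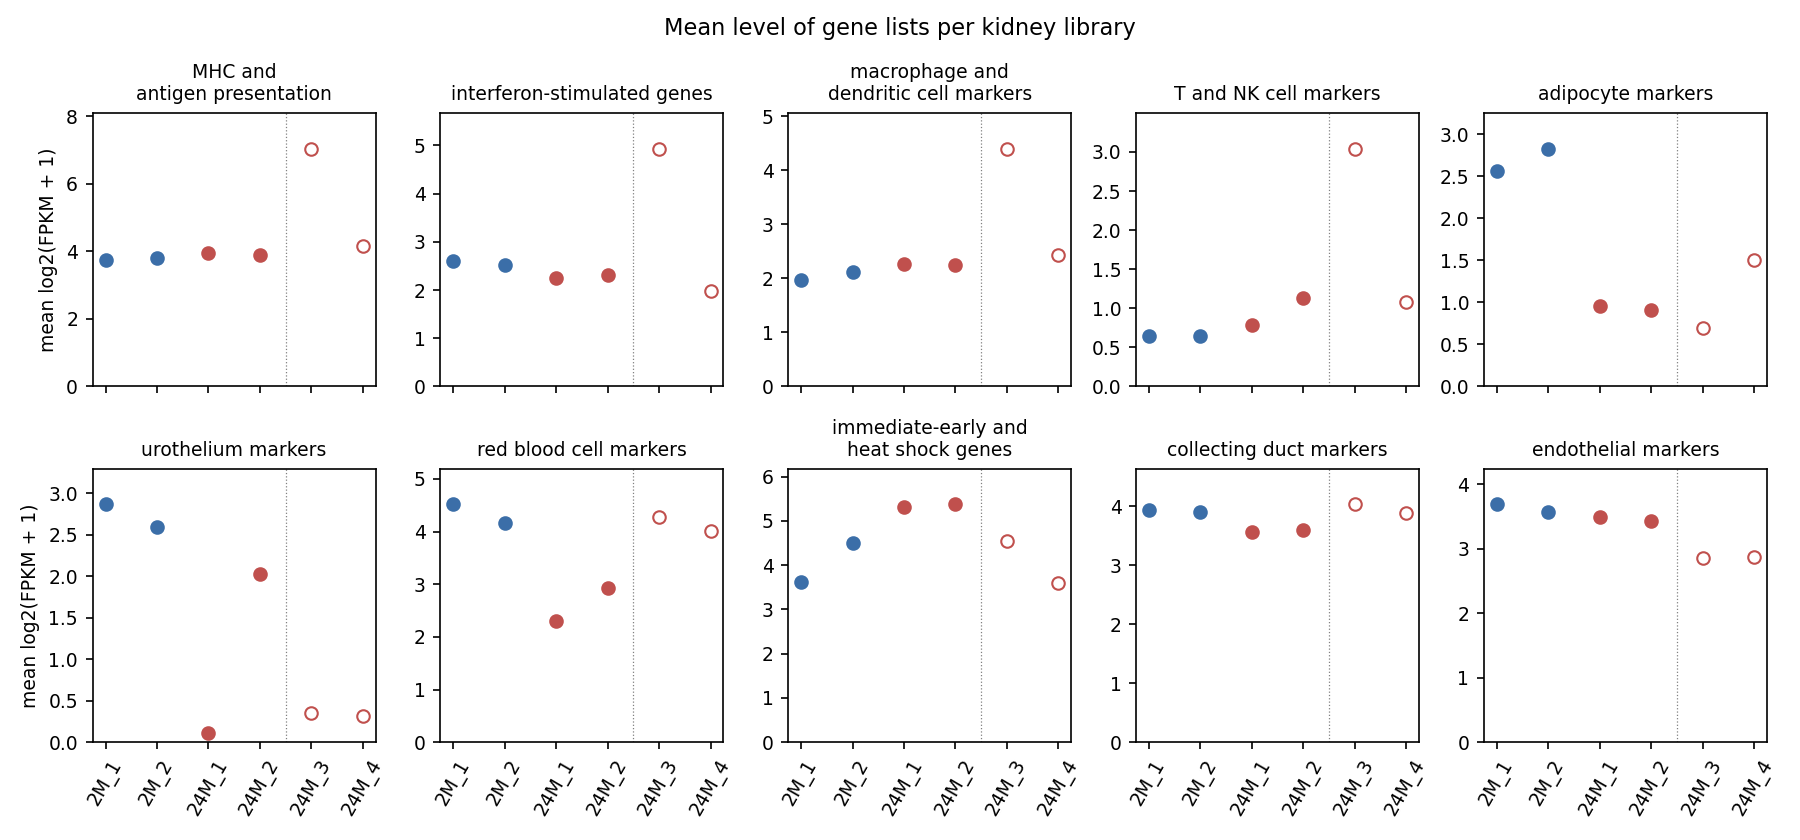
Mean log2(FPKM + 1) of 10 gene lists over genes in both tables (vertical axes, each starting at 0) in each kidney library (horizontal axes). Blue points are 2M, filled red points are 24M libraries of the tested table, and open red points right of the dotted line are 24M libraries of the separate table. 24M_3 lies at 7.04 in the antigen presentation list, where the other 24M libraries lie between 3.89 and 4.16.

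The calls of the tested table were set beside the separate table. Of the 87 genes higher in 24M, 61 (70.1%) had both 24M_3 and 24M_4 above both 2M libraries, against 32.0% of 11241 uncalled genes. Of the 90 lower genes listed there, 70 (77.8%) had both below, against 40.4% of uncalled genes. Both comparisons use the same 2M libraries, and in 50 simulations of unchanged genes the leading genes gave shares of 49.0% (36.8% to 59.8%) and 54.6% (44.4% to 63.3%). Both observed shares lie above the highest of these simulations, which rest on an assumed spread of each gene. The simulations also draw every gene independently, whereas real genes can move together, so the simulated range may be too narrow. Standing above it is therefore not evidence of replication. The shares are not independent of the calls, and the 2 libraries of 2M could not be split between the comparisons.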

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

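The tests of library-wide scaling, of lymphoid tissue and of reads shared between defensin genes were chosen only after the results they bear on were seen. Those on a further fat list and a further intestine list also address patterns already seen. They were written before these further lists were evaluated as sets. Single members belong to results already seen. Cox8b of the further fat list is among the largest decreases. Tff3, Itln1 and Zg16 of the further intestine list are among the genes listed only in the separate table, where the intestinal pattern was seen. The further lists are therefore not independent of those patterns. Outlying libraries were sought among the 4 libraries of 24M in 55 levels, of 40 list means and 15 genes, and chance alone would single out about 1 in 20. In all, 7 levels had a library far from the other 3, of which 5 were in 24M_3. The levels join tables that were made separately.

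24M_3 stood apart in 5 immune lists. Its mean log2(FPKM + 1) over genes in both tables was 7.04 for MHC and antigen presentation (3.89 to 4.16 in the other 24M libraries), 4.93 for interferon-stimulated genes (1.97 to 2.32) and 4.48 for complement (2.91 to 3.14). It was 4.40 for macrophage and dendritic cell markers (2.25 to 2.44) and 3.04 for T and NK cell markers (0.785 to 1.13). Single genes, chosen after their values were seen, were B2m at 2038 FPKM against 329 in 24M_4, Iigp1 at 309 against 2.03, and Ccl5 at 74.0 against 2.94. The granzyme gene Gzma, not listed in the tested table and also chosen after its values were seen, stood at 13.8 FPKM in 24M_3 and 0.468 in 24M_4.

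A scaling difference between 24M_3 and 24M_4 is argued against, since the median log2 difference over all genes of the separate table was 0.13 and that of the antigen presentation list 2.87. Of 20 transcripts abundant in resting lymphocytes 16 were listed, 15 of them higher in 24M_3 than in 24M_4 and 1 lower, with medians of 1.31 and 0.493 FPKM, led by Cd52, chosen after its values were seen, at 51.8 and 13.0 FPKM; 4 of the 16 were at 1 FPKM or more in a 2M library. The median in 24M_3 is 0.016 of the median antigen presentation excess of 81.4 FPKM, but that ratio was not measured in lymphoid tissue, so lymphoid tissue in the 24M_3 sample stays open. Activated immune cells and an interferon response of kidney cells stay open as candidate explanations too, and neither was tested. The design names no group that separates 24M_3 from 24M_4, so no biological explanation was tested.

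The separate table held 32 genes at 10 FPKM or more that the tested table does not list, whose age-group means there had to reach about 0.50 FPKM. Of these, 21 were higher in 24M_4, led by alpha-defensins, the antimicrobial peptides of Paneth cells. The summed FPKM of 19 alpha-defensin genes was 560 in 24M_4 and 8.05 in 24M_3, with Defa24 at 121 FPKM, and the intestinal fatty acid binding protein gene Fabp2 stood at 32.4 FPKM in 24M_4 and 0.263 in 24M_3, both genes chosen after their values were seen. Reads shared between near-identical defensin genes do not account for Fabp2, which was 123 times as high in 24M_4 as in 24M_3. In a further list of 35 intestinal genes 19 were listed, and the median log2 difference between 24M_4 and 24M_3 was 1.27, with 18 higher and 1 lower; genes are not independent replicates and each side is 1 library, so no p is given. The 10 members outside the tested table had a median of 2.16 with 10 higher. At 0.227 FPKM or less in 24M_3, they had little room to be lower in 24M_4, so their direction carries little weight. The 9 members also in the tested table, all at 1 FPKM or more in a 2M kidney library, had a median of 0.40 with 8 higher. This is consistent with small intestine RNA in the 24M_4 library, as a hypothesis. No biological explanation was tested, since the design sets nothing apart in 24M_4.

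Urothelium markers stood apart in 24M_2, at a mean log2(FPKM + 1) of 2.02 against 0.105 to 0.353 in the other 24M libraries. Mitochondrially encoded genes stood apart in 24M_4, at 11.94 against 11.40 to 11.47. This level includes mt-Atp6, at 4154.5 and 4320.3 FPKM in 24M_1 and 24M_2 but 899 and 1447 in 24M_3 and 24M_4. That gene lowers the 24M_3 mean, so the flag may rest on a difference between tables. The search was not repeated without it.

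Adipocyte markers were lower in 24M_1 and 24M_2 than in the 2M libraries, at a median log2 change of -1.48. A library-wide scaling difference is argued against, since the median change of all genes tested was -0.024. If less fat had been carried in the 24M samples, a further fat list of 25 genes would also be lower. The 14 tested members had a median log2 difference of -0.15, with 12 lower and 2 higher. That size lies between the bounds set for and against this cause before the list was evaluated, so the test leaves it open. All 14 were at 1 FPKM or more in a 2M kidney library. Lpl, chosen after its values were seen, stood at 79.3 and 98.1 FPKM in 24M_1 and 24M_2, where Adipoq was at 0. Such members can hide a loss of fat in the median. Cox8b fell from 7.67 and 4.04 FPKM in 2M to 0 in 24M_1 and 24M_2. Car3, also chosen after its values were seen, fell from 32.4 and 36.3 to 15.7 and 9.11. An effect of age on fat in the kidney is open too, was not tested, and cannot be told apart from a difference in dissection because all 24M libraries share the age.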

How the results depend on the processing

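The count of genes past the threshold (180, with 87 higher and 93 lower) stayed within 1.5 times under pseudocount 0.1, no filter, both scalings, non-robust moderation and an unadjusted p with a log2 change of at least 1, where it ranged from 132 to 176. Adding a log2 change of at least 1 to the FDR left 78 (33 higher, 45 lower), by construction. Leaving out a replicate gave counts from 0 (either 2M library) to 126, with 0 to 36 higher and 0 to 91 lower; fewer libraries leave 1 residual degree of freedom. With the replicate block the count was 43 (25 higher, 18 lower), 36 of them among the 180. Deviations of 2M_1 and 24M_1 from their age means had a correlation across genes of -0.059. With 2 libraries per age, 2M_2 and 24M_2 give the same value by construction. This value cannot show whether same-numbered libraries share more than a number. Among alternatives added after seeing the data, the fit without intensity trend gave 122 genes with 56 higher, the cause was not tested, and protein-coding genes alone gave 180. Of 2241 recomputed values of 176 named genes, 179 lost and 11 gained the threshold and none of the called values changed sign. Many named genes were uncalled in the main fit and could not lose the threshold, so 179 of 2241 understates the share of calls lost. Among uncalled values 26 changed sign, and these were not treated as reversals. Mcu was below 0 and uncalled under every setting, at -0.27 to -0.01. The count of lists (13) became 0 with an estimated correlation (smallest adjusted p 0.564) and 0 with fry (0.0942), which tests each list against no change; with fry in either direction 25 passed. It was 11 by ranks, 17 without filter, 13 with the replicate block and 11 to 15 with a library left out. The adipocyte list had 1 tested member without 2M_1 or 2M_2 and gave no value there. Count-based alternatives (size factors, upper quartile, other count models, count filters) and a choice between tables did not apply to FPKM with different libraries per table, and leaving out 24M_3 or 24M_4 does not touch the fit. The unknown depth limits what can be said of genes listed at 0.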

Other observations

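Genes with near-equal values within an age in the tested table did not all keep that level in the separate table. Afmid, at 25.5 and 25.1 FPKM in 24M_1 and 24M_2, stood at 15.4 in 24M_3 and 5.24 in 24M_4, the latter below the 2M values of 6.90 and 6.95. Mob1a, at 4.87 and 5.22 FPKM in 24M_1 and 24M_2, stood at 7.32 and 0.731. By contrast Cyp2d12 stood at 310 and 319 FPKM, above 123 and 141 in 24M_1 and 24M_2, and Thrsp at 1.31 and 1.30, below 2.33 and 2.29.

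Some transcripts differed between the tables more than between ages. The mitochondrially encoded mt-Atp6, chosen after its values were seen, was at 3953 to 4533 FPKM in the tested table and at 899 and 1447 in 24M_3 and 24M_4. Rps2 was at 109 to 125 FPKM in the tested table and at 254 and 297 in the separate table. Levels of Hspa1a, a heat shock gene chosen after its values were seen, were 20.6 FPKM in 2M_1, 37.0 in 2M_2, 214 in 24M_1 and 112 in 24M_2, against 6.93 and 6.98 in 24M_3 and 24M_4.

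Sex-biased kidney genes did not move alike between the libraries. The male-biased Slco1a1 was at 94.9 and 118 FPKM in 2M, 60.01 and 57.5 in 24M_1 and 24M_2, and 6.74 and 36.0 in 24M_3 and 24M_4 of the separate table. Acsm3 followed with 135 and 149, then 81.8 and 65.7, then 17.2 and 73.7. The male-biased Cyp2e1, chosen after its values were seen, was at 261 and 289, then 284 and 302, then 347 and 558. The female-biased Slc7a12 was at 1.204 and 0.619 FPKM in 2M, 7.24 and 6.62 in 24M_1 and 24M_2, and 23.3 and 8.05 in 24M_3 and 24M_4. The female-biased Slc22a7 was at 76.5 and 65.0, then 41.9 and 41.2, then 7.32 and 52.8.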
